A study of Homo sapiens with 22 samples.

How the data were processed

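ChIP-seq of HIRA, H3.3 and H4K16ac in IMR90 fibroblasts gave 8 deposited peak lists, 1 per group, and 1 deposited table of H4K16ac differences. HIRA was precipitated with a mixture of 4 antibodies and H3.3 through an HA tag, per the labels. The 2 H4K16ac libraries of each state were made with 2 different antibodies, the same pair in both states, per the labels. Groups and replicate numbers were taken from the sample labels. Input libraries and libraries of total H4 were not analysed here as measurements of their own. Nothing in the labels says whether the H4K16ac replicates came from separate cultures, so the authors' p-values measure the spread between those libraries, which may be technical.

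Reads were handled by the authors with CASAVA 1.8.2, Trim Galore 0.3.0, Bowtie2 2.1.0, SAMtools 0.1.16, Picard 1.98, SICER 1.1, DiffBind 1.8.3 and DESeq and placed on hg19, per the submitters' processing notes, which name these tools without saying which step each served. The deposited peak lists hold chromosome, start and end and no score. All H3.3 and H4K16ac peaks start on a grid of 200 bp, and HIRA peaks do not, so these lists were not made with the same caller or setting, and which caller made which list, its threshold and its control are not given in the sources used here. HIRA and H3.3 lists were taken as per-sample calls, since each group has 1 library. The H4K16ac lists cover 2 libraries each, and how these were combined is not given in the sources used here. These lists contain 209 and 505 peaks of 1 bp. Grid coordinates may be off by 1 base, because the files do not say whether counting starts at 0 or at 1.

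The deposited H4K16ac table gives a concentration per state on the log2 scale, the log2 fold as Young minus Old, a p-value and an FDR, per the file headers. It holds no column per library. The authors' table lists 52857 regions with an FDR up to 0.1, and the number tested, 127800, was worked out from the relation between its p-values and FDR values. Young and Old were read as proliferating and replicative senescent, the only states in which H4K16ac was mapped. Folds are printed here as Old minus Young. The lowest log2 concentration in the authors' table, -2.18 in Young and -0.85 in Old, recurs in many regions and was treated as a floor. The normalization behind these concentrations is not given in the sources used here. A planned test per library could not be made from this table.

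Peaks on chromosomes 1 to 22 and X were analysed, and peaks on other sequences were left out. Lists were compared by the share of peaks of one list that overlap the other by at least 1 bp. The share was set against 1000 circular shifts of one list along its chromosomes, after removal of stretches over 1 Mb without any peak in any list. Shares have 95% Wilson intervals, which cover counting error only, and peaks are not independent observations. No read counts are in the files, so depth per sample is unknown, and a peak missing from a list may lie below that list's threshold. A difference in the number of peaks between lists can come from depth or threshold.

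Genes were taken from GENCODE release 44 on GRCh37, the same assembly as hg19. Of 20098 annotated protein-coding genes, 19478 had a canonical transcription start site, and 7 with a duplicate symbol were dropped, leaving 19471. A promoter was the start site with 1000 bp on either side (2001 bp). For the share of promoters with a peak, the promoter windows were shifted instead of a list, over whole chromosomes and without removal of empty stretches, which lowers the shifted share. The gene lists, the main test of each comparison, the rule for named genes and the settings listed at the end, except the restriction to regions above the floor, were fixed before the data were examined. Splits by GC decile, peak class and quiet promoters, counts over joined lists and separate loci, and the tests of explanations were added later. The 18 lists were senescence-associated secreted factors (30 genes), p53 targets and cell cycle inhibitors (23), E2F targets and cell division genes (34), replication-dependent histone genes (63), HIRA, H3.3 and H4K16 machinery (23), cytoplasmic ribosomal protein genes (79), fibroblast and extracellular matrix genes (30), lysosome and autophagy genes (25), interferon and NF-kB response genes (24), RAS-MAPK response genes (20), housekeeping genes (23), Wnt pathway genes (23), markers of epithelial (13), endothelial (10), blood (15), neuronal (13) and hepatocyte cells (14), and olfactory receptor genes (371). FAS and PECAM1 were listed but not found under these symbols. Each list's net change was placed among 10000 random lists of the same size, matched on the GC content of 500 bp on either side of the start site in 10 bins. Matching took no account of peaks in the reference state, although a bound member cannot gain a peak and an unbound one cannot lose one. A list is called outside the matched range when it lies outside the central 95% of random lists. With 18 lists in each comparison, about 1 list would lie outside by chance.

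Named genes were 12 context genes, then per list and comparison up to 2 members per direction with a promoter peak in only 1 state and the most covered bases, the genes at the 5 widest promoter peaks of each list, the 10 regions of lowest FDR per direction in the authors' table that overlap a gene, and up to 4 members per list past the authors' FDR of 0.05. Some of these were left out of the text for length, and some are not reported here. H4K16ac folds of the authors' table in regions that overlap HIRA or H3.3 were set against other regions, weighted to match on deciles of width and mean concentration but not on GC content. Ranges come from 10000 draws of the medians of bound and of matched regions, with regions taken as independent.

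The shift test and the gene-list test on the share of bound members were tried on simulated data. With 0%, 30% and 60% of 65632 proliferating HIRA peaks placed on H3.3 peaks, the shift test recovered 0.0789%, 29.8% and 60.2%. For gene lists, 100 simulated lists of 30 genes were given proliferating HIRA promoter peaks at random, at 0%, 30% or 60% of members, bound already or not. The share of bound members lay above the matched range in 4%, 44% and 93% of these lists, so a moderate excess in a list of this size is often missed. The test of the net change between states was not simulated. Alternatives were an overlap of at least 50%, peaks at least as wide as the list's median, shifts over whole chromosomes, peaks away from start sites, promoter windows of 500 bp and 2 kb, no GC matching, other FDR thresholds, and for bound regions no matching, the proliferating list, regions outside promoters and, added after the data were seen, regions above the floor. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9.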

Results

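Chromatin immunoprecipitation and sequencing (ChIP-seq) was used to map the histone chaperone HIRA, the replacement histone H3.3 and histone H4 acetylated at lysine 16 (H4K16ac) in IMR90 cells, an established line of human fibroblasts with a limited replicative lifespan. HIRA is the core subunit of a complex that deposits H3.3 into chromatin outside DNA replication. H4K16ac is an acetylation mark of open chromatin. The design asked how the 3 were distributed in proliferating and in senescent cells. Senescence is a lasting exit from the cell cycle, reached after many divisions (replicative senescence) or after activation of an oncogene (oncogene-induced senescence, OIS). The series held 22 samples. HIRA was mapped in 1 library each of proliferating, replicative senescent, OIS and OIS control cells, H3.3 in 1 library each of proliferating and replicative senescent cells, and H4K16ac in 2 libraries of each of these states. The 6 input libraries and the 3 libraries of total H4 in each state were not analysed here on their own. The labels do not say in which state the OIS control cells were.

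Each of the 8 groups was represented by 1 list of peaks, so differences between lists had no replicate check and no p-value was computed across peaks or genes. The lists give positions without read counts, and the depth of each library is unknown. For HIRA, 65647 peaks were listed in proliferating cells, 121907 in replicative senescent cells, 113697 in the OIS control and 112378 in OIS. These peaks were narrow, with median widths of 281, 248, 294 and 296 bp, and covered 33.1, 45.2, 58.9 and 54.5 Mb. H3.3 lay in 77387 peaks in proliferating and 96732 in replicative senescent cells, both with a median width of 1801 bp, covering 174 and 224 Mb. For H4K16ac, the list of proliferating cells held 15245 peaks over 20.4 Mb and that of replicative senescent cells 66321 peaks over 80.9 Mb, with a median width of 1001 bp in both.

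All 8 lists were concentrated at the promoters of protein-coding genes, taken as 1 kb on either side of the transcription start site. HIRA had a promoter peak at 11207 of 19471 genes in proliferating cells (57.6%), 13166 in replicative senescence (67.6%), 9579 in the OIS control (49.2%) and 9601 in OIS (49.3%). H3.3 was listed at 12279 promoters in proliferating cells (63.1%) and 12693 in replicative senescence (65.2%). H4K16ac was listed at 4347 promoters in proliferating cells (22.3%) and at 12215 in replicative senescence (62.7%). When the promoter windows were shifted along whole chromosomes, stretches without peaks included, the mean share of windows hit was between 1.91% and 13.7%. At the HIRA gene itself (hg19, chromosome 22, 19318221 to 19434973), HIRA peaks covered 1003 bp of the 2001 bp promoter window in proliferating cells and 1322 bp in replicative senescence, against 796 bp in the OIS control and 794 bp in OIS. ALB, which encodes the hepatocyte protein albumin, had no promoter peak in any of the 8 lists.

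**Figure D1:**
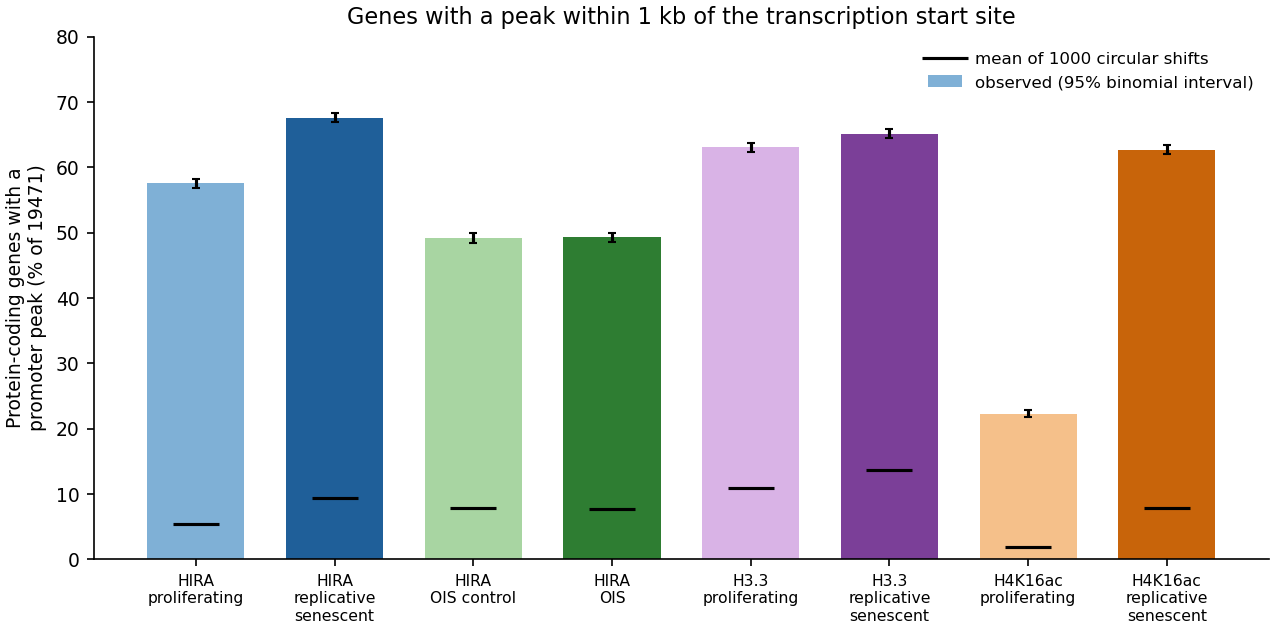
Percentage of 19471 protein-coding genes with a peak within 1 kb of the transcription start site, per peak list, with 95% binomial intervals and, as black lines, the mean of 1000 circular shifts of the promoter windows over whole chromosomes. H4K16ac went from 22.3% to 62.7% of genes and HIRA from 57.6% to 67.6% between proliferating and replicative senescent cells, while the OIS control and OIS lists stood at 49.2% and 49.3%.

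HIRA in replicative senescence was compared with proliferating cells first. Replication-dependent histone genes, which supply histones for S phase, had HIRA promoter peaks at 41 of 63 members in both states, at 14 in proliferating cells only and at 0 in senescent cells only. H3C12 and H3C8, both histone H3 genes on chromosome 6, had the whole 2001 bp window covered in proliferating cells and none of it in senescence. Cytoplasmic ribosomal protein genes had a peak only in proliferating cells at 13 of 79 members, among them RPL4 (1348 bp) and RPL37A (1121 bp), and only in senescence at 1, RPS3 (319 bp). Among markers of neurons the opposite held, with 7 of 13 members bound only in senescence and 0 only in proliferating cells. Of these 7 genes, those with the most covered bases were RBFOX3, a splicing factor of neuronal nuclei (1095 bp), and GAD2, which makes the transmitter GABA (895 bp). Markers of blood cells had 6 of 15 members bound only in senescence, including the T-cell kinase gene LCK (1006 bp) and SPI1, a transcription factor of myeloid and B cells (887 bp).

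For each list, the number of members bound only in senescence minus the number bound only in proliferating cells was set against 10000 random gene lists matched on promoter GC content, since 3254 genes genome-wide had a HIRA promoter peak only in senescence, 1295 only in proliferating cells and 9912 in both. The histone list stood at -14 where matched lists had a median of 3 (central 95%, -5 to 10; percentile 0). Ribosomal protein genes stood at -12 against 8 (-1 to 17; percentile 0.005). Neuronal markers stood at 7 against 1 (-2 to 5; percentile 99.9) and blood markers at 6 against 1 (-2 to 5; percentile 99.5). Random lists were not matched on binding in proliferating cells, so these percentiles also depend on how many members could gain or lose a peak. Only 1 ribosomal protein gene gained a peak and 2 had none in either state, so a net change of 8 could not be reached. By losses alone, 13 ribosomal protein genes lost the peak and 63 kept it. Among histone genes 14 lost it and 41 kept it, against 1295 and 9912 genome-wide. Of genes unbound in proliferating cells, 3254 genome-wide gained a peak and 5010 did not, a share to which the neuronal and blood gains were not compared. Because neighbouring histone genes share windows, the histone list was also counted as 42 separate loci, of which 37 had a HIRA peak in proliferating and 28 in senescent cells. The blood result was inside the central 95% with a 2 kb window (percentile 97.4) and with the wider peaks of each list (percentile 95.005).

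Fibroblast and extracellular matrix genes had 24 of 30 members bound in both states, 4 in proliferating cells only and 0 in senescence only (percentile 0.42). COL5A2, a fibrillar collagen gene, had 1130 bp and DCN, which encodes the matrix proteoglycan decorin, had 1027 bp covered in proliferating cells and none in senescence. E2F targets and cell division genes had 27 of 34 members bound in both states. The mitotic cyclin genes CCNA2 (1145 bp) and CCNB1 (859 bp) were among the 4 bound only in proliferating cells, and the replicative helicase gene MCM6 (639 bp) and the proliferation marker MKI67 (437 bp) were the 2 bound only in senescence (percentile 1.27, and 8.16 with a 500 bp window). In both lists few members were left to gain a peak, with 2 fibroblast genes and 1 E2F gene unbound in either state. The matched medians of 3 and 4 could therefore not be reached, and the low percentiles partly reflect this. Genome-wide, 88.4% of genes with a proliferating HIRA promoter peak kept one in senescence. Of 23 housekeeping genes, GUSB (289 bp) and TBP (188 bp) were bound only in proliferating cells and 0 only in senescence (percentile 1.59, but 5.79 with a 500 bp window, 5.69 with the wider peaks and 2.94 without GC matching). Of 371 olfactory receptor genes, which are silent in most tissues, 13 were bound only in senescence and 2 only in proliferating cells. OR5C1 (347 bp) and OR1K1 (346 bp), neighbours on chromosome 9, led the former, and the list lay at percentile 99.5 with GC matching but at percentile 0.16, on the opposite side, without it.

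The remaining lists lay inside the central 95% of matched lists. Senescence-associated secreted factors had 17 of 30 members bound in both states, 4 only in senescence and 1 only in proliferating cells (percentile 60.5). The stress cytokine gene GDF15 (903 bp) and the colony-stimulating factor gene CSF2 (542 bp) were bound only in senescence, and the chemokine gene CCL2 (237 bp) only in proliferating cells. Among 23 p53 targets and cell cycle inhibitors, 18 were bound in both states (percentile 18.1). CDKN2A, the locus of the INK4A and ARF inhibitors (chromosome 9, 21967751 to 21995300), had 681 bp covered only in senescence and CDKN1C, another inhibitor of cyclin-dependent kinases, 405 bp. PPM1D, a phosphatase gene that dampens p53 signalling (691 bp), and the p53 target SESN1 (358 bp) were bound only in proliferating cells. Genes of the HIRA, H3.3 and H4K16 machinery had 18 of 23 members bound in both states (percentile 3.97, and 0.69 with a 500 bp window), with MSL3 (697 bp) bound only in senescence and PML (808 bp) and the deacetylase gene SIRT1 (332 bp) only in proliferating cells. Lysosome and autophagy genes (percentile 30.5) had 5 of 25 members bound only in senescence, including the protease genes CTSZ (914 bp) and CTSD (913 bp), and 3 only in proliferating cells, including TFE3 (791 bp). Interferon and NF-kB response genes (percentile 29.4), RAS-MAPK response genes (percentile 22.1) and Wnt pathway genes (percentile 30.1) had 3 of 24, 1 of 20 and 3 of 23 members bound only in senescence, and 2, 0 and 1 only in proliferating cells. HBEGF, a ligand of the EGF receptor (576 bp), was the RAS-MAPK gene, and the Wnt ligand gene WNT2 (810 bp) and the receptor gene FZD1 (453 bp) led the Wnt list. Epithelial, endothelial and hepatocyte markers lay at percentiles 58.4, 53.1 and 92.4, with the tight junction gene CLDN3 (818 bp), EGFL7 (487 bp) and the apolipoprotein gene APOA1 (655 bp) bound only in senescence, and CLDN4 (1005 bp) and TEK (709 bp) bound only in proliferating cells.

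**Figure D2:**
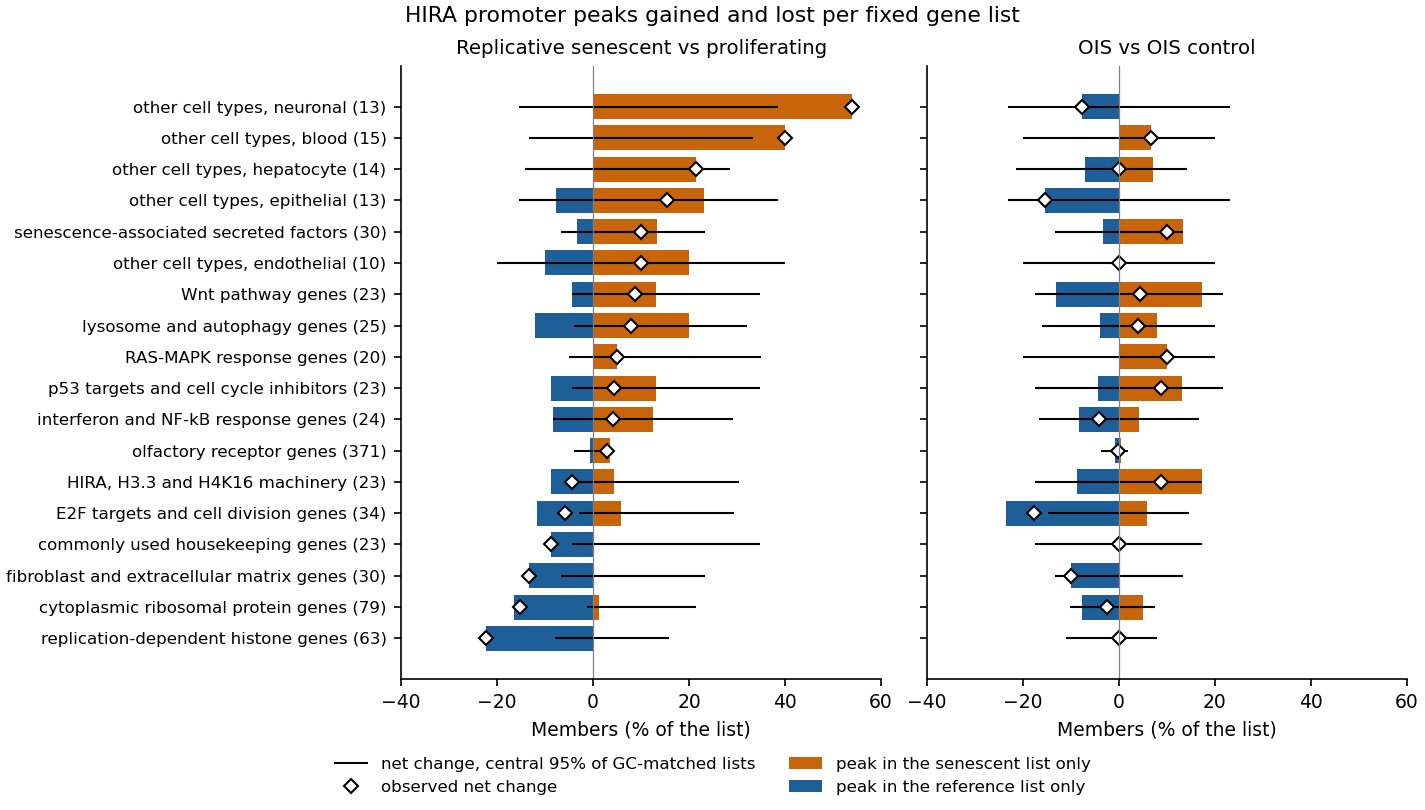
Members of each fixed gene list with a HIRA promoter peak in the senescent list only (orange, to the right) or the reference list only (blue, to the left), as a percentage of the list, whose size is in brackets. Diamonds are the net change and black lines the central 95% of the net change of 10000 GC-matched random lists, and in replicative senescence histone genes (-14 of 63) and neuronal markers (7 of 13) lie outside on opposite sides. The random lists were not matched on binding in the reference list.

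As sets of regions, 29835 of 121881 senescent HIRA peaks overlapped a proliferating HIRA peak by at least 1 bp (24.5%, 95% Wilson interval 24.2% to 24.7%). The mean over 1000 circular shifts was 2.62% and the highest 3.23%, so that the overlap was 9.35 times the shifted mean. The 92046 senescent peaks outside proliferating peaks had a median width of 225 bp, and 11.8% of them lay at promoters. Those that overlapped a proliferating peak had a median width of 392 bp, and 41.7% lay at promoters. The share of genes with a HIRA promoter peak went with promoter GC content, a split made after the lists were seen. In the decile of lowest GC it was 5.80% in proliferating and 4.16% in replicative senescent cells, and in the decile of highest GC 76.1% and 92.9%.

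**Figure D3:**
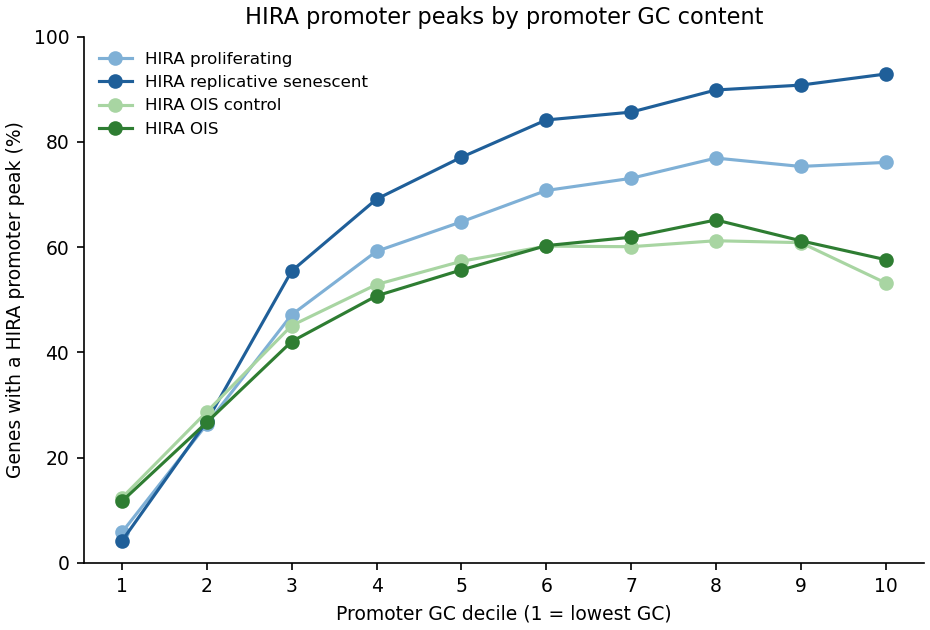
Percentage of protein-coding genes with a HIRA promoter peak in each decile of promoter GC content, from lowest to highest, for the 4 HIRA lists. In the top decile the replicative senescent list reached 92.9% and the proliferating list 76.1%, against 53.2% in the OIS control and 57.6% in OIS.

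HIRA in oncogene-induced senescence was compared with its own control. E2F targets and cell division genes had 20 of 34 members bound in both, 8 in the control only and 2 in OIS only. CCNB1 (450 bp) and CDK1, the kinase that drives entry into mitosis (307 bp), were bound only in the control, and TYMS, which makes thymidylate for DNA synthesis (401 bp), and CCNE2 (184 bp) only in OIS. Secreted factors had 23 of 30 members bound in both, 4 only in OIS and 1 only in the control. Those bound only in OIS with the most covered bases were CSF2 (1303 bp) and the inflammatory cytokine gene IL1A (1117 bp). All 54 histone genes that were bound in the control were also bound in OIS. DUSP4, a phosphatase that inactivates ERK (1631 bp), and SPRED2, an inhibitor of RAS signalling (504 bp), were the RAS-MAPK genes bound only in OIS.

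Set against GC-matched random lists, the net change of the E2F list was -6 (matched median 0, central 95% -5 to 5; percentile 0.975). With a 500 bp window (percentile 20.4) or the wider peaks (percentile 3.98) it was inside the range. The other 17 lists were inside it, with secreted factors at percentile 91.9, p53 targets at 78.1, histone genes at 67.3, ribosomal protein genes at 39.5, fibroblast genes at 9.38 (2.17, outside, with the wider peaks), the HIRA, H3.3 and H4K16 machinery at 78.9, lysosome genes at 61.4, interferon and NF-kB genes at 29.5, RAS-MAPK genes at 81.5, housekeeping genes at 47.3 and Wnt genes at 62.1. Among these, CDKN2A (278 bp), ZMAT3 (400 bp), the H4K16 acetyltransferase gene KAT8 (1225 bp), SIRT2 (346 bp), RPL21 (1317 bp), UVRAG (398 bp) and the secreted Wnt antagonist genes DKK3 (1194 bp) and SFRP1 (351 bp) were bound only in OIS. CDKN2B (299 bp), the acetyltransferase gene KAT5 (356 bp), CABIN1, a subunit of the HIRA complex (317 bp), RPS20 (821 bp), the matrix genes COL3A1 (1594 bp) and LUM (1258 bp), ISG15 (297 bp), TCF7L2 (765 bp) and WNT2 (627 bp) were bound only in the control. Epithelial, endothelial, blood, neuronal and hepatocyte markers lay at percentiles 10.7, 51.0, 75.5, 26.0 and 54.0 and olfactory receptor genes at 68.8. KRT18 (302 bp) and CLDN4 (492 bp) were the epithelial genes bound only in the control, and the monocyte gene CD14 (201 bp) was the blood gene bound only in OIS.

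Genome-wide, HIRA promoter peaks were listed for 7879 genes in both OIS and its control, 1722 in OIS only and 1700 in the control only, a difference of 0.113 percentage points. This difference was 2.72 points with a 500 bp window and -0.457 points with the wider peaks. Of 112369 OIS peaks, 52340 overlapped a control peak (46.6%, shifted mean 4.02%, highest 4.35%), which was 11.6 times the shifted mean.

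The HIRA peaks of both kinds of senescence were then set side by side. At the promoter of the inflammatory cytokine gene IL6, HIRA covered 900 bp in proliferating and 761 bp in replicative senescent cells, against 2001 bp in the OIS control and 1662 bp in OIS. CXCL8, another secreted inflammatory factor, had no HIRA promoter peak in proliferating or replicative senescent cells, 927 bp in the OIS control and 1820 bp in OIS. CDKN2A had HIRA bases in both kinds of senescence (681 bp and 278 bp) and in neither reference list. Of 121881 HIRA peaks in replicative senescence, 22731 overlapped an OIS peak (18.7%, shifted mean 3.73%, highest 4.22%), which was 5.01 times the shifted mean. A similar share, 19.1%, overlapped the OIS control list. Of 7118 genes without a HIRA promoter peak in either reference list, 322 had one in both kinds of senescence, where 252 were expected within GC deciles if the contrasts were independent (ratio 1.28). Of 8433 genes with a peak in both reference lists, 199 had none in either kind of senescence, where 137 were expected (ratio 1.45). Both restrictions were chosen after the data were seen, and the strength of the peaks was not accounted for. Over all genes, without these restrictions, 311 and 118 were expected within GC deciles (ratios 1.04 and 1.68). Apart from these counts, differences between the contrasts were not tested.

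For H3.3, most promoters listed in proliferating cells were also listed in replicative senescence (94.99%). Fibroblast genes had an H3.3 promoter peak at 29 of 30 members in both states, histone genes at 54 of 63, p53 targets at 22 of 23, RAS-MAPK genes at 20 of 20, housekeeping genes at 21 of 23 and Wnt genes at 22 of 23, with 0 members in 1 state only in each of these lists. MKI67 (715 bp) and E2F2, a transcription factor of the cell cycle (1402 bp), were among the 3 E2F genes with H3.3 only in senescence. The lysosomal regulator TFEB (1656 bp) and CTSD (845 bp), the antiviral gene OAS1 (1001 bp), the metalloproteinase gene MMP10 (801 bp), RPL21 (1295 bp), RPL11 (1096 bp), CLDN3 (1402 bp) and the blood markers CD79A (1749 bp) and CD8A (801 bp) were also listed only in senescence. Only in proliferating cells were IL1A (932 bp), the chromatin remodeller gene ATRX (401 bp), ATP6V1H (1201 bp) and SERPINA1 (2001 bp) listed.

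None of the 18 lists lay outside the central 95% of GC-matched lists for H3.3, with percentiles from 12.7 for hepatocyte markers and 12.8 for the HIRA, H3.3 and H4K16 machinery to 89.1 for E2F targets and 92.6 for blood markers. In total 11664 genes had an H3.3 promoter peak in both states, 1029 in senescence only and 615 in proliferating cells only, a difference of 2.13 points that was 0.390 points with the wider peaks. Of 96732 senescent H3.3 peaks, 63259 overlapped a proliferating one (65.4%, shifted mean 11.9%, highest 12.7%), 5.50 times the shifted mean. When at least 50% of the peak had to be covered, it was 9.72 times the shifted mean.

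H4K16ac was compared between the same 2 states, and most of its senescent promoter peaks were listed in senescence only. Replication-dependent histone genes had an H4K16ac promoter peak at 18 of 63 members in both states and at 39 in senescence only, among them the neighbours H2BC26 (2001 bp) and H2AC25 (1774 bp) on chromosome 1. All 23 measured p53 targets and cell cycle inhibitors had a peak in senescence, 17 of them in senescence only, such as PLK3 (2001 bp) and TP53INP1 (1996 bp). Secreted factors had 17 of 30 members with a peak only in senescence, including the adhesion molecule gene ICAM1 (2001 bp) and the cytokine gene IL6 (1983 bp), and interferon and NF-kB genes 14 of 24, including the transcription factor genes IRF7 and IRF1 (2001 bp each). CDKN1A, the main p53-induced cell cycle inhibitor, had 1402 bp covered in senescence and none in proliferating cells. MKI67 showed the opposite, with 915 bp in proliferating cells and none in senescence, and was the E2F gene with a peak in proliferating cells only.

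Against GC-matched lists, 4 lists had more members with a peak only in senescence than the central 95%. These were histone genes (39 net, matched median 17, range 11 to 25; percentile 100), secreted factors (17 against 10, 6 to 15; percentile 99.6), p53 targets (17 against 11, 7 to 16; percentile 98.97) and interferon and NF-kB genes (14 against 9, 5 to 13; percentile 98.6). Without GC matching the secreted factors (percentile 96.2) and the interferon genes (percentile 95.7) were inside the range, as were the interferon genes with a 2 kb window (percentile 89.9) and with the wider peaks (percentile 95.4). Markers of endothelial, blood, neuronal and hepatocyte cells and olfactory receptor genes had fewer, while epithelial markers lay inside the range. Endothelial markers had 0 of 10 members with a peak only in senescence (percentile 0.49), blood markers 1 of 15 (SPI1, 104 bp; percentile 1.02), neuronal markers 1 of 13 (the synaptic gene SYT1, 401 bp; percentile 0.58), hepatocyte markers 0 of 14 (percentile 0.92) and olfactory receptor genes 3 of 371 (percentile 0). Blood markers with the wider peaks (percentile 2.87), neuronal markers with a 2 kb window (percentile 2.94) and hepatocyte markers under both settings (percentiles 39.8 with a 2 kb window and 2.64 with the wider peaks) were inside the range.

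Fibroblast genes (15 of 30 in senescence only; percentile 96.9), RAS-MAPK genes (13 of 20; percentile 90.9), the HIRA, H3.3 and H4K16 machinery (13 of 23; percentile 78.3), ribosomal protein genes (35 of 79; percentile 76.2), lysosome genes (14 of 25; percentile 74.5), Wnt genes (13 of 23; percentile 70.7), housekeeping genes (10 of 23; percentile 31.4), E2F genes (14 of 34; percentile 13.9) and epithelial markers (4 of 13; percentile 13.4) lay inside the range. Every ribosomal protein gene and every machinery gene had a peak in senescence, 44 and 10 of them in both states. Their net changes could therefore not have been larger. With the wider peaks the machinery (percentile 99.6), ribosomal protein genes (99.96) and E2F genes (0.025) lay outside the range, as did RAS-MAPK genes without GC matching (98.4). Among them COL5A1, TWIST1, EPHA2, DUSP5, RPL8, RPS2, CTSB, FZD2 and AXIN1 had all 2001 bp covered in senescence and none in proliferating cells, and the H3.3 gene H3-3A (1985 bp) and the HIRA complex gene UBN1 (1882 bp) nearly all. Genome-wide, 4291 genes had an H4K16ac promoter peak in both states, 7924 in senescence only and 56 in proliferating cells only, a difference of 40.4 points. Of 66267 senescent peaks, 9278 overlapped a proliferating one (14.0%, shifted mean 1.86%, highest 2.24%), 7.54 times the shifted mean.

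The authors also tested H4K16ac between states in regions, and labelled the states Old and Young, read here as replicative senescent and proliferating. In the authors' deposited table, which gives a log2 concentration per state, H4K16ac at CCND1, the cyclin D gene, was 1.86 in Young and 8.51 in Old (chromosome 11, 69448601 to 69466201, FDR 1.79e-20). The authors' deposited table gave CDKN1A 3.31 and 6.88 (FDR 3.23e-05), HIRA 3.82 and 7.06 (FDR 6.00e-09), COL1A1 5.02 and 8.48 (FDR 0.000775), ACTB 2.31 and 7.93 (FDR 1.41e-06) and GAPDH 5.22 and 9.24 (FDR 0.0126). LMNB1, a nuclear lamina gene, went from 2.66 to 4.57 (FDR 0.00355) and IL6 from 3.54 to 5.52 (FDR 0.00392) in the authors' deposited table. MKI67 was lower in Old in the authors' deposited table, at 2.44 in Young and -0.85 in Old, the lowest Old value listed (FDR 0.00395). CDKN2A, at the table's floor of -2.18 in Young, had 5.47 in Old in the authors' deposited table (FDR 4.42e-16).

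At the authors' FDR of 0.05, the authors' deposited table listed 37665 regions higher in Old and 4459 higher in Young, of 127800 tested, so that 89.4% were higher in Old. In the same authors' deposited table the number higher in Young was 1157 at an FDR of 0.01 and 7463 at 0.1. The Old-higher regions of the authors' deposited table had a median difference of 3.72 log2 units (quartiles 3.07 and 4.69) and a median GC content of 53.4%, and 35.8% of them lay at promoters. Of these, 45.4% were at the table's floor in Young in the authors' deposited table, where the size of the difference depends on the floor. Regions higher in Young in the authors' deposited table had a median difference of -2.59, a median GC content of 46.7% and promoter overlap in 3.21%, and 85.5% of them were at the table's floor in Old.

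The regions of lowest FDR in the authors' deposited table were all at the floor in Young and had Old concentrations of 8.54 at CYB5D1, NAA38 and TMEM88 with the histone demethylase gene KDM6B (chromosome 17, 7744601 to 7763201), 8.53 in the retinoid receptor gene RXRA (chromosome 9, 137286601 to 137331601) and 8.48 at the lactate transporter gene SLC16A3 (chromosome 17, 80181601 to 80212001). In the authors' deposited table they were followed by COL5A1 (8.42), LASP1 (8.39), ELL (8.34), KDM4B (8.30), IFI30 with PIK3R2 and MAST3 (8.22), RALGDS (8.17) and RASA3 (8.17), each with an FDR of 1.31e-25. Among regions higher in Young, the authors' deposited table had gene-body regions of PDE4DIP, a centrosome and Golgi protein gene (chromosome 1, 145056801 to 145061201), at 4.34 in Young (FDR 4.31e-08) and FRMD5 (chromosome 15, 44177401 to 44184601) at 4.29 (FDR 3.22e-07), with Old at its lowest listed value. CDC27 (3.25), TENM4 (3.33), NAV2 (3.19), CIT (3.18) and NOD1 (3.16) came next in Young in the authors' deposited table.

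**Figure D4:**
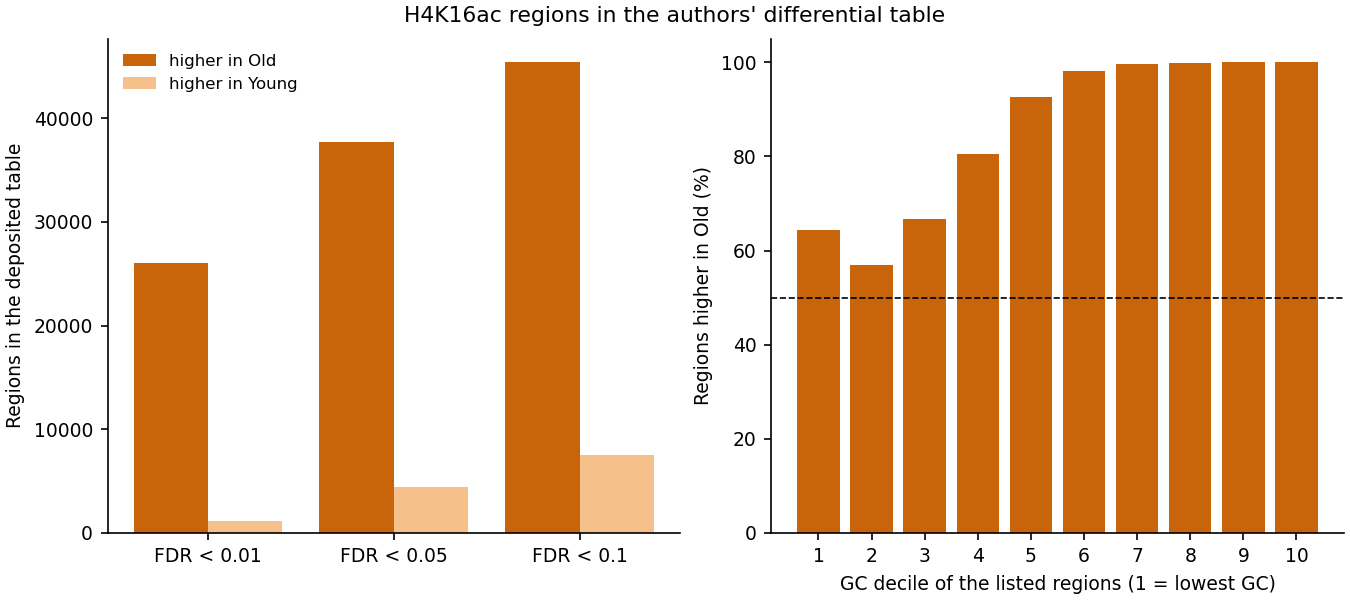
Left, number of regions in the authors' deposited H4K16ac table higher in Old (orange) or Young (light) at 3 FDR thresholds, with 37665 and 4459 at 0.05. Right, percentage of listed regions higher in Old in each decile of GC content, from 56.9% in the second decile to 100% in the tenth, with a dashed line at equal numbers.

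Promoters of 12843 genes (66.0%) overlapped a region higher in Old in the authors' deposited table and those of 27 genes a region higher in Young. By list, the authors' deposited table had higher H4K16ac in Old at the promoters of 78 of 79 ribosomal protein genes (percentile 100 of GC-matched lists), 45 of 63 histone genes (percentile 100.0), 24 of 30 fibroblast genes (99.97), all 25 lysosome genes (99.9), all 23 of the HIRA, H3.3 and H4K16 machinery (99.9), all 23 p53 targets (99.8), all 23 housekeeping genes (99.7), all 23 Wnt genes (99.7) and 19 of 24 interferon and NF-kB genes (98.9). RAS-MAPK genes (19 of 20; 95.8), secreted factors (20 of 30; 93.7) and E2F genes (28 of 34; 68.1) were inside the matched range in the authors' deposited table, as were epithelial (7 of 13; 2.83) and hepatocyte markers (3 of 14; 2.60). Fewer than matched lists in the authors' deposited table were neuronal (4 of 13; 0.125), blood (4 of 15; 0.715) and endothelial markers (1 of 10; 0.015) and olfactory receptor genes (4 of 371; 0).

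Of genes above the floor, the authors' deposited table gave the secreted factor IGFBP7 2.22 in Young and 6.21 in Old, TP53INP1 1.79 and 6.70, the methyltransferase gene EZH2 0.64 and 5.07, the helicase gene MCM4 2.35 and 5.79, and the shared promoter of H3C1 and H4C1 1.78 and 5.82. UBN1 had 1.84 and 6.50 and MSL2, of an H4K16 acetyltransferase complex, 2.81 and 6.96 in the authors' deposited table. Further values in the authors' deposited table were -0.36 and 6.01 for IRF1, 0.29 and 6.44 for the MAPK-responsive gene ETV5, 1.84 and 6.18 for TWIST1, 2.64 and 6.72 for PPIA and 0.90 and 5.64 for KRT18. Genes at the floor in Young in the authors' deposited table included VEGFA (7.87 in Old), BBC3 (7.82), GDF15 (5.54), RPS2 (8.60), COL6A1 (8.28), ULK1 (8.14), JUN (6.63), EGR1 (6.65) and DVL1 (9.72).

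The last comparisons set HIRA, H3.3 and H4K16ac against each other within a state. COL1A1, the main collagen gene of fibroblasts, lay in one of the widest promoter peaks of all 4 HIRA lists (37770 bp in proliferating cells, 25467 bp in replicative senescence, 24925 bp in the OIS control and 21968 bp in OIS) and of both H3.3 lists (33601 bp and 45601 bp). PLEC, which encodes the cytoskeletal linker plectin, had the widest HIRA promoter peak in proliferating cells (chromosome 8, 144976553 to 145021716, 45164 bp), replicative senescence (36860 bp) and OIS (28437 bp). In the OIS control the widest was over HOXB2, HOXB3, HOXB4 and HOXB5, developmental transcription factor genes (chromosome 17, 46616303 to 46675627, 59325 bp), followed by COL1A2 (38967 bp). The matrix gene THBS1 (17603 bp in replicative senescence), the filamin gene FLNA (28320 bp in proliferating cells), and INHBA (22119 bp) and WNT5A (16344 bp) in OIS were also among the 5 widest of their lists. The widest H3.3 promoter peak lay at NEK6 in senescence (53801 bp). For H4K16ac, the widest promoter peaks in both states lay at SPDYE2 and UPK3BL2 on chromosome 7 (41401 bp and 33001 bp). Both genes have a near-identical copy nearby, SPDYE2B and UPK3BL1, so that reads cannot be assigned between the copies with certainty. EME2 with MRPS34, NME3, NUBP2 and SPSB3 shared a wide peak in senescence in the H4K16ac list (25401 bp) and the HIRA list (16737 bp).

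**Figure D5:**
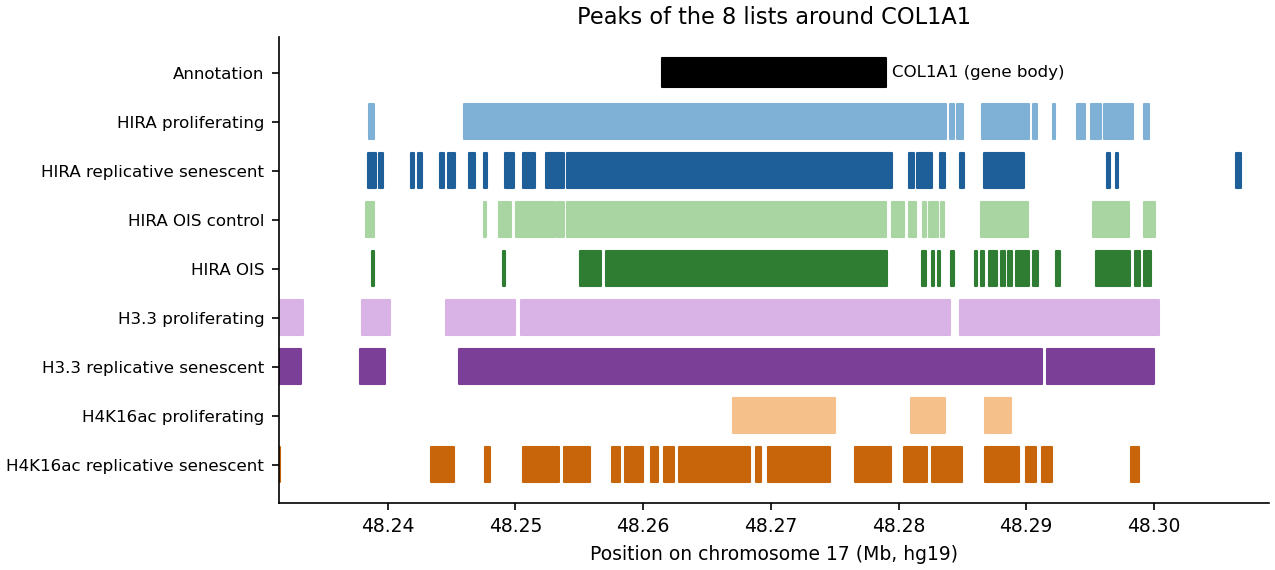
Peaks of the 8 lists (coloured blocks) around COL1A1 (black block) by position on chromosome 17 in Mb, hg19. HIRA and H3.3 peaks cover the gene body in all 4 HIRA and both H3.3 lists, with HIRA peaks of 37770 bp in proliferating and 25467 bp in replicative senescent cells, and H4K16ac peaks are more numerous in senescence.

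Of 65632 proliferating HIRA peaks, 43102 overlapped an H3.3 peak (65.7%), 7.89 times the shifted mean of 8.33%, and in replicative senescence 50682 of 121881 did (41.6%), 4.02 times the shifted mean of 10.4%. HIRA peaks that overlapped H4K16ac numbered 7117 in proliferating cells (10.8%, 8.44 times the shifted mean of 1.28%) and 37066 in senescence (30.4%, 5.75 times the shifted mean of 5.29%). H4K16ac peaks lay in H3.3 peaks in 51.6% of cases in proliferating cells (4.86 times the shifted mean) and 53.7% in senescence (4.07 times). All of these overlaps were above the highest of 1000 shifts. Senescent HIRA peaks that overlapped a proliferating HIRA peak lay in H3.3 peaks in 81.1% and in H4K16ac peaks in 68.4% of cases, and those outside proliferating peaks in 28.8% and 18.1%. At promoters, all 3 marks were listed together at 3678 genes in proliferating cells, where 1578 were expected if they were independent, and at 9648 in senescence, where 5384 were expected.

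In the authors' deposited table, regions that overlapped a senescent HIRA peak had a median difference of 3.85 log2 units between Old and Young, against 2.85 in regions matched on width and mean level, a difference of 1.00 (0.98 to 1.04 over 10000 draws of both medians, with regions taken as independent). Among regions of the authors' deposited table above the floor in Young, an alternative chosen after the data were seen, this difference was 0.54, and with the proliferating HIRA list it was 0.25. Regions with an FDR above 0.1 are not listed in the authors' deposited table, so the medians of bound and matched regions leave out unchanged regions. Of listed regions that overlapped a senescent HIRA peak, 98.1% were higher in Old, against 75.5% of the others before matching. The difference may partly reflect this mix of directions. GC content was not matched. In the authors' deposited table, regions higher in Old had a median GC content of 53.4% and those higher in Young 46.7%. Senescent HIRA peaks had a median of 61.2% where they overlapped a proliferating peak and 57.7% elsewhere. A link of the difference to HIRA can therefore not be told apart from one to GC content. For H3.3-bound regions of the authors' deposited table the difference was 0.04 (0.01 to 0.06), but -0.0600 with the proliferating H3.3 list (-0.0890 to -0.0327), -0.0308 outside promoters (-0.0668 to 0) and -0.00562 above the floor (-0.0283 to 0.0175), so that the last 2 ranges reached or spanned 0. Without matching, the H3.3-bound difference in the authors' deposited table was 0.49 (0.48 to 0.53).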

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

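The tests of a loss or gain common to both kinds of senescence, of scaling, of region GC content and of control reads were chosen after the values behind their results were seen, the test with equal peak numbers was added after a test on wider peaks had been seen, and the tests on window size and peak width at histone and ribosomal protein genes were chosen before.

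Several measures of the HIRA lists had opposite signs in the replicative senescence and OIS contrasts, and these differences were not tested. The number of HIRA peaks was 56249 higher in replicative senescence than in proliferating cells and fell by 1321 from the OIS control to OIS. The length covered was 12.1 Mb larger in replicative senescence and fell by 4.44 Mb in OIS, and the median peak width fell by 33 bp in replicative senescence and was 2 bp larger in OIS. Net HIRA promoter change in replicative senescence and OIS was 7 and -1 for neuronal markers, 11 and -1 for olfactory receptor genes, and 19 and -2 for the 65 markers of other cell types joined, but with a 2 kb window the OIS values were 0, 2 and 1, so these opposite signs depended on the window. Peaks on the mitochondrial sequence, which no comparison used and where the H3.3 lists have none, numbered 7 in proliferating HIRA, 10 in replicative senescent HIRA, 6 in the OIS control and 8 in OIS, 4 in proliferating H4K16ac and 3 in senescent H4K16ac.

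Of 65 markers of other cell types, 21 had a HIRA promoter peak only in replicative senescence and 2 only in proliferating cells, an excess over GC-matched lists that lay in neuronal (percentile 99.9) and blood markers (99.5, but 95.005 with the wider peaks), while epithelial (58.4), endothelial (53.1) and hepatocyte markers (92.4) were inside the matched range. For weak peaks counted at a looser threshold, only the 65632 widest senescent peaks were used, as many as in the proliferating list. Width stood in for strength because the lists have no scores. Of the joined markers, 15 were then bound only in senescence and 2 only in proliferating cells (percentile 99.99). The percentile cannot decide this, because only the senescent list was trimmed. The matched median fell from 6 to -1 with the trimming, and markers unbound in proliferating cells could not lose a peak. Hepatocyte markers were outside the range in that setting (percentile 98.5). A gain common to both kinds of senescence was not seen at 1 kb in OIS (net -2, percentile 29.7), but a smaller one is not excluded by the 2 kb window (net 1, percentile 67.4). Weak peaks counted at a looser threshold and binding at the start may each account for the excess and stay open. So may senescence itself and a property of the single senescent library, such as its depth or background.

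At histone and ribosomal protein genes joined (142 genes), 27 had a HIRA promoter peak only in proliferating cells and 1 only in replicative senescence. Peaks displaced to just outside the window would restore the count with a 2 kb window. With that window 26 genes still had a peak only in proliferating cells and 0 only in senescence, so the count was not restored. The percentile of the net change there (0) cannot decide this, because a net change of 0 would also lie below the matched range (1 to 25). Weak proliferating peaks would be narrow, but the lost genes' median widest peak (954 bp) stood at percentile 75.5 of all proliferating promoter peaks, although the 104 members with a senescent peak too had wider ones (2048 bp). Genome-wide, genes that lost the peak also had narrower ones than genes that kept it (medians of 322 bp and 553 bp). A part of weaker peaks in the loss is therefore not excluded. A loss common to both kinds of senescence was not seen at 1 kb in OIS (percentile 53.9), but a smaller one is not excluded by the 2 kb window (net -7, percentile 17.7). The percentiles of net change also depend on binding in proliferating cells, which was not matched. Of the joined genes bound there, 27 lost the peak and 104 kept it, against 1295 and 9912 genome-wide. Senescence itself and a property of 1 of the 2 libraries may each account for the loss and stay open.

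H4K16ac was higher in Old at 89.4% of regions past the authors' FDR of 0.05. A scaling offset the size of the gap between the floors (1.33 log2 units) was not decided: once it was taken off, 5976 regions were 4 log2 units higher in Old and 2002 in Young (ratio 2.99), but these reached an FDR of 0.0968, so weaker regions may be missing from the list. Region GC content stays open, since the share of listed regions higher in Old was lowest at 56.9% in the second GC decile and rose to 100% in the tenth, a gradient that a GC bias between libraries or a mark at GC-rich regions would both give. On control reads taken off wide regions, the share of listed regions at the Young floor fell from 64.0% in the narrowest to 17.8% in the widest decile. The median Old concentration of regions at that floor rose from 1.13 to 6.11 between the same deciles, so the trend with width does not decide this. Of regions past the authors' FDR of 0.05 and above both floors, 96.9% were higher in Old. This explanation stays open, because 45.4% of Old-higher and 85.5% of Young-higher regions past that FDR were at a floor and values above it can be lowered as well. A rise of H4K16ac in senescence, a difference in scaling or depth, and a difference in the yield of the precipitations may each account for the direction and stay open.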

How the results depend on the processing

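Restriction to regions above the Young floor was chosen after the data were seen, and all other tests here were planned. No paired analysis was possible because the H4K16ac table has no column per library. For the same reason the planned test per library was not run, nor were its alternatives (a replicate block, DESeq2, other pseudocounts, a filter on low regions, each replicate left out, other FDR thresholds of that test). FDR thresholds of the authors' deposited table were varied. A minimum log2 fold of 1 changed no count, since every region past the FDR exceeds it, and says nothing about stability. Depth is unknown for every list, which limits any comparison of peak numbers. Where a value moved below, the cause was not tested.

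All 44 overlap alternatives stayed above the shifts, from 3.71 to 16.7 times the shifted mean. With at least 50% of the peak covered, the overlap was 11.6 times the shifted mean for HIRA in replicative senescence with proliferating cells, 16.7 for OIS with its control, 5.67 for both kinds of senescence, 9.72 for H3.3 and 10.98 for H4K16ac between states, 9.18 and 4.40 for HIRA with H3.3 (proliferating, senescent), 9.54 and 6.62 for HIRA with H4K16ac, and 6.43 and 5.08 for H4K16ac with H3.3. With peaks at least as wide as each list's median, in the same order, it was 13.6, 16.7, 6.87, 6.80, 8.91, 10.1 and 5.36, 10.3 and 8.01, and 5.88 and 5.02. With shifts over whole chromosomes it was 10.3, 12.5, 5.47, 5.94, 8.36, 8.59 and 4.40, 9.29 and 6.39, and 5.30 and 4.46. With peaks over 1 kb from a start site it was 10.4, 13.3, 4.67, 6.91, 7.97, 8.81 and 3.71, 6.58 and 5.66, and 4.03 and 4.01.

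Regions higher in Young numbered 1157 at an FDR of 0.01 and 7463 at 0.1 in the authors' deposited table. The HIRA-bound difference was 0.87 with at least 50% of the region covered, 0.25 with the proliferating list, 1.13 outside promoters and 0.54 above the floor. The H3.3-bound difference was 0.49 without matching, had the opposite sign with the proliferating list (-0.0600, range -0.0890 to -0.0327), and was -0.0308 outside promoters (-0.0668 to 0) and -0.00562 above the floor (-0.0283 to 0.0175), ranges that reached or spanned 0. The promoter difference was 10.9 points for HIRA in replicative senescence with a 2 kb window, 2.72 for HIRA in OIS with a 500 bp window, and 0.390 for H3.3 and 36.6 for H4K16ac with the wider peaks.

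Of 288 percentiles of gene lists under an alternative, 263 stayed on their side of the matched range, 16 came inside it, 8 went outside it and 1 changed sides. Inside it came, for HIRA in replicative senescence, E2F genes with a 500 bp window (8.16), housekeeping genes with a 500 bp window (5.79), the wider peaks (5.69) and no GC matching (2.94), and blood markers with a 2 kb window (97.4) and the wider peaks (95.005). Olfactory receptor genes changed sides without GC matching (0.16), a setting that compares them with genes of any promoter GC content. In OIS, E2F genes came inside with a 500 bp window (20.4), which left 0 lists outside, and with the wider peaks (3.98). For H3.3, a 500 bp window put 1 list outside, hepatocyte markers (2.45). For H4K16ac, secreted factors came inside without GC matching (96.2), interferon genes with a 2 kb window (89.9), the wider peaks (95.4) and no GC matching (95.7), blood markers with the wider peaks (2.87), neuronal markers with a 2 kb window (2.94) and hepatocyte markers with a 2 kb window (39.8) and with the wider peaks (2.64). Lists that went outside included the HIRA, H3.3 and H4K16 machinery for HIRA in replicative senescence (0.69 with a 500 bp window, 0.80 with the wider peaks), fibroblast genes in OIS (2.17 with the wider peaks) and, for H4K16ac, the machinery (99.6), ribosomal protein genes (99.96) and E2F genes (0.025) with the wider peaks and RAS-MAPK genes (98.4) without GC matching.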

Other observations

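The motif test below was chosen before its result was seen, and its split by peak class, the split by quiet promoters and the floor values were chosen after.

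A set of 5206 protein-coding genes had no H3.3 or H4K16ac promoter peak in either state. At these promoters HIRA peaks were listed for 358 genes in proliferating cells (6.88%), 1615 in replicative senescence (31.02%), 108 in the OIS control (2.07%) and 109 in OIS (2.09%). At the other 14265 genes the shares were 76.1%, 81.0%, 66.4% and 66.5%.

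HIRA peaks listed in replicative senescence but not in proliferating cells had a median GC content of 57.7%, and 7.71% of them overlapped an OIS peak and 7.29% a peak of the OIS control. HIRA peaks listed in proliferating but not in replicative senescent cells had a median GC content of 50.2%, and 38.8% of them overlapped an OIS peak and 45.4% a peak of the OIS control.

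Regions higher in Old in the authors' deposited table were densest on chromosomes 19 (35.4 per Mb), 17 (27.6), 22 (20.9) and 16 (19.2). The genes used here numbered 24.1, 14.1, 8.40 and 9.27 per Mb on these chromosomes. Chromosome 11, with 9.51 genes per Mb, had 14.5 such regions per Mb, and a link to gene density was not tested. The share of listed regions at the Young floor in the authors' deposited table was 64.0% in the narrowest decile and 17.8% in the widest.

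AP-1 is a family of stress- and growth-responsive transcription factors with the binding motif TGASTCA (S is C or G). The hypothesis that HIRA peaks away from promoters lie at AP-1 sites in every state predicted at least 1.5 times as many motifs in the central 200 bp of such peaks as in flanks 2 kb away. The ratio was 2.59 in proliferating cells, 1.91 in the OIS control and 1.72 in OIS, but 1.17 in replicative senescence, the lowest, so the prediction did not hold there, while the reversed motif stayed between 0.965 and 1.23. By class, it was 1.03 in replicative senescent peaks outside proliferating peaks, 1.79 in those that overlapped one, 2.92 in proliferating peaks outside senescent peaks and 1.93 in those that overlapped one. In the OIS contrast it was 1.34 in OIS peaks and 1.38 in control peaks outside the other list, and 2.23 and 2.60 in those that overlapped it. Unshared peaks thus had the lower ratio in 3 of the 4 lists, and weak or unspecific peaks were not separated from peaks at other sites. The motif was not particular to HIRA, with a ratio of 2.33 in distal senescent H3.3 peaks, and in replicative senescent HIRA peaks the CTCF core (1.79) and E-box (1.35) motifs had higher ratios than AP-1.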
